A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

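Transcript levels of Bradyrhizobium diazoefficiens USDA 110 were compared on 6 arrays with 2 dye channels each. Each array held cDNA of a culture grown by arabinose-supplemented chemoautotrophy and of a culture grown heterotrophically. The cultures came from 3 independent preparations per condition. Every replicate number had 2 arrays, with the dyes Cy3 and Cy5 exchanged between the conditions. Per the labels' protocols, total RNA was extracted with hot phenol, 10 µg of it was primed with random hexamers and reverse transcribed, and 2 µg of cDNA went into each labelling. The scanner, the background correction, the normalization method and any filter are not given in the sources used here.

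The deposited values are log2 ratios of the 2 channels of an array, normalized by the authors, per the labels. The table had 8480 rows, of which 8040 had a value on all 6 arrays. Per the labels, every value is the ratio of arabinose-supplemented chemoautotrophy over heterotrophy. The values went against that on 1 of the dye orientations: the 2 arrays of a replicate correlated across genes at -0.858, -0.847 and -0.938 in replicates 1, 2 and 3, while arrays of the same orientation correlated at 0.53 to 0.781. The orientations therefore run in opposite directions in the deposited table, and the stated ratio does not settle which of them follows it. The array titles name the Cy3 condition first, so their order flips with the sign. Read as first over second they give Cy3 over Cy5, but whether the order states a ratio or only the dyes is not given. The sign of the 3 arrays with heterotrophy in Cy3 was turned, so that all 6 ran the same way. With that sign, hupL (bll6941), the large subunit of the uptake hydrogenase, is positive. Positive values are called the hydrogenase side and negative ones the opposite side throughout, with no condition attached to either. The array medians of the deposited values lay between -0.0874 and 0.02, and their SDs between 0.639 and 0.858. Spot intensities were not used here, so signal over background is unknown and the number of arrays limits the precision.

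Row names are locus tags. Symbols came from the platform annotation, a table of an older date, which lists 8462 of the 8480 rows with 1 symbol each, does not list 18 and gives several genes for 0. For 1469 rows the symbol was other than a locus tag. The RefSeq table given with the series shared 0 gene IDs with that annotation and was not used for names or positions. Rows of a gene were averaged per array, which gave 8268 genes, 192 of them with more than 1 row. Of these, 171 had 2 or more complete rows, whose first 2 rows correlated at 0.172 across genes, and in 25 genes the rows differed by more than 1 on the log2 scale. No gene named by the rule given here had more than 1 row. The 7853 genes with a value on all 6 arrays were tested, and 415 were not.

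The 2 arrays of a replicate hold the same pair of extracts, so their mean counted as 1 replicate (n = 3). Mean log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and an adjusted p under 0.05. The fit had 2 residual and 3.22 prior degrees of freedom. An exact sign-flip test on 3 replicates cannot go below p = 0.25. A dye effect was tested in the same way on the 3 differences between the 2 arrays of a replicate. The replicate numbers pair the arrays: the deviations of same-numbered arrays from their orientation's mean correlated at 0.739, 0.713 and 0.707 across genes, against -0.513 to -0.265 for differently numbered arrays. The values below 0 follow from subtracting that mean once same-numbered arrays correlate above 0, and are no separate evidence of the pairing.

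Before the data were examined, 28 gene lists were fixed by patterns on symbols and product names. No product names were used here, so lists were matched on symbols alone, and the lists for aminoacyl-tRNA synthesis and amino acid ABC transporters matched 0 genes. The 24 lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was also run with an estimated correlation. That run takes its p-values from a t distribution with the 2 residual degrees of freedom, so few lists could pass after adjustment whatever their correlation. Fry was run too, which asks whether the genes of a list move, on balance, one way, without comparing them with other genes. The counts per list are given over all genes tested, and also adjusted over the list alone where that count differs or the list was called.

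The genes named were fixed by a rule: the 10 largest changes on each side among genes with an adjusted p under 0.05, the same sign on all 6 arrays and a symbol, the largest on each side whatever the name, and per list the 2 largest passing on each side or, where none passed, the 2 with the smallest p. For the Calvin cycle, hydrogenase, carbon monoxide dehydrogenase, nitrogen fixation and tricarboxylic acid cycle lists the 8 members with the smallest p were added. The rule named 87 genes. Outside it, and chosen after their values were seen, are cbbY, dnaJ, exoT, exoB, glnK, gltB, nifH, atpD and both atpA genes in the results, and the genes of runs, of symbol groups and of differences between replicates in the closing section.

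Alternatives fixed beforehand were the replicate block as a random effect with and without a dye term, all 6 arrays taken as independent, each dye orientation alone, centring, scaling to a common median absolute deviation, genes with a value in at least 2 replicates, robust eBayes, rows tested on their own, an adjusted p under 0.01, limma's treat against a 1.5-fold change, and leaving out each replicate. Added after seeing the data were the fit with no array turned, the hydrogenase list without hupA and split by tag block, and fry with the replicate block. Figures were drawn with matplotlib 3.10.9.

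The procedure was tested on simulated data for the comparison of the 2 conditions over 7853 genes, with each gene's own spread and 50 genes changed at each fold. It called 0% of the genes changed 1.5-fold, 40% of those changed 2-fold, 84% of those changed 4-fold and 94% of those changed 8-fold, all with the right sign. Among the unchanged genes it called 4, and with no gene changed it called 0. A simulated shift of the ribosomal protein list was called, and with no list shifted 0 of 24 lists were called. Simulated genes were drawn independently of each other, while the estimated correlation within a list reached 0.49 in the data (chaperones and heat shock). The simulation therefore cannot tell how often camera at its preset correlation calls unshifted lists of correlated genes. The dye test recovered 99.5% of 200 simulated dye effects, with 6 calls among the other genes. These effects added 2 on the log2 scale to the arrays with heterotrophy in Cy3 and took 2 from the others. The observed median absolute differences between the arrays of a replicate were 0.141 to 0.26, and recovery at such sizes was not tested.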

Results

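Bradyrhizobium diazoefficiens USDA 110 is a soil bacterium that forms nitrogen-fixing nodules on soybean and can also grow as a chemoautotroph, taking energy from hydrogen and carbon from carbon dioxide. The series asked which of its genes differ in transcript level between arabinose-supplemented chemoautotrophy and heterotrophy, growth on organic carbon. RNA of 3 independent culture pairs was hybridised to 6 arrays of 2 channels, with each pair on 2 arrays of exchanged dyes. Between 8211 and 8444 of the 8480 rows had a value on each array. The measurement is a normalized log2 ratio per gene, so it gives differences between the conditions and no transcript level in either.

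The changed hydrogenase and Calvin cycle genes had the same sign on all arrays of 1 dye orientation and the other sign on all arrays of the second. The 2 arrays of a replicate correlated at -0.858, -0.847 and -0.938 across genes, although the labels define every value as the same ratio. If the labels hold on the arrays with heterotrophy in Cy5, where the deposited ratio is then Cy3 over Cy5, the hydrogenase side means higher under arabinose-supplemented chemoautotrophy. If they hold on the arrays with heterotrophy in Cy3, where the ratio is Cy5 over Cy3, the hydrogenase side means lower under that condition. The array titles name the Cy3 condition first, and read as a ratio that order gives the first of these readings. Whether the order states a ratio or only the dyes is not given. The direction is therefore not settled, and sizes are given by side. Sizes, tests and the relation of one gene to another hold under both readings.

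**Figure D1:**
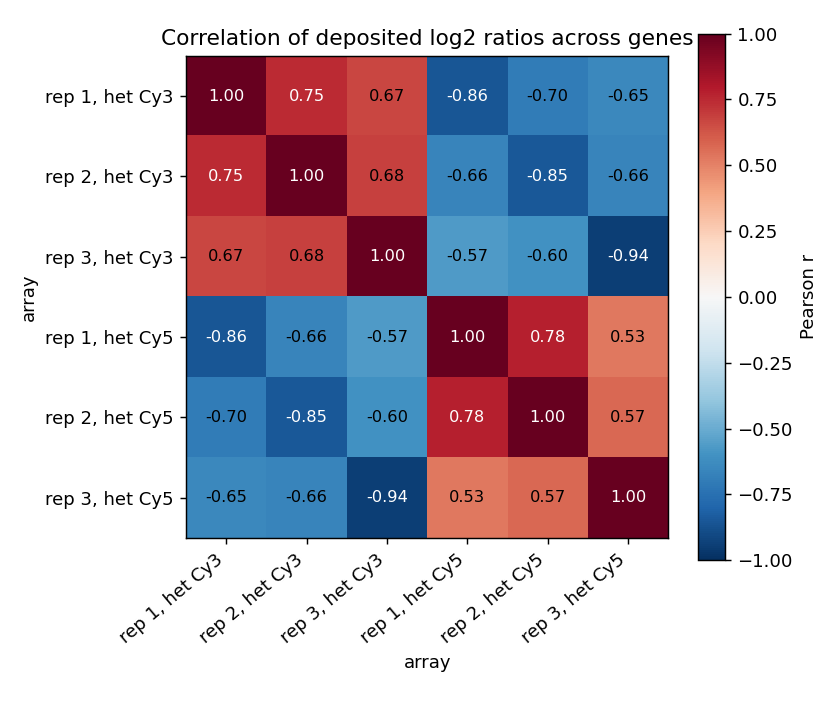
Pearson correlations across genes between the 6 arrays, computed on the deposited log2 ratios. Rows and columns are arrays, named by replicate and by the dye that labelled the heterotrophic culture (het). Arrays of the same orientation correlate above 0, at 0.53 to 0.781, and arrays of opposite orientation below 0, reaching -0.938 in replicate 3.

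Changed genes for hydrogen uptake, carbon dioxide fixation and the ATP synthase stood on one side, and a fixK regulator gene with bioB and panD had the largest sizes on the other among genes with a symbol. Between the 2 conditions, 885 of 7853 genes changed (11.3%, limma, Benjamini-Hochberg adjusted p under 0.05), 530 on the hydrogenase side and 355 on the opposite side. All 885 had the same sign on all 6 arrays. At least 2-fold changes numbered 524, with 307 on the hydrogenase side and 217 on the opposite side. The largest on the hydrogenase side was blr2455, at a log2 size of 5.10 ± 0.60 (SD, n = 3), or 34.3-fold, and the largest on the opposite side was bll7411, at 6.24 ± 0.27, or 75.6-fold. Neither has a symbol in the annotation. Symbols other than locus tags were available for 171 of the changed genes. The count rests partly on replicate 2: without it 221 genes passed. A fit of 2 replicates has fewer degrees of freedom and takes part of its variance from all genes. A call lost without a replicate, here and below, therefore need not mean that the gene itself differs in that replicate. In a fit of all 6 arrays with the replicate block as a random effect 1825 genes passed, 1085 on the hydrogenase side and 740 on the other, including 884 of the 885.

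Among changed genes with a symbol, 2 genes of the uptake hydrogenase, which oxidises hydrogen to feed electrons into respiration, had the largest sizes, hupC and hupS. The cytochrome subunit gene hupC (bll6940) changed by a log2 size of 4.49 ± 0.78 (SD, n = 3, 22.5-fold, adjusted p = 0.0053). The gene of the small subunit, hupS (bll6942), changed by 4.35 ± 0.39 (20.3-fold, adjusted p = 0.00335), and that of the large subunit, hupL (bll6941), by 3.05 ± 0.26 (8.27-fold, adjusted p = 0.00335). Genes for the assembly of the enzyme's nickel-iron centre lay on the same side, with hypA (bll6932) at 2.19 ± 0.63, hypC (bsl6929) at 1.81 ± 0.10 and hypB (bll6931) at 1.72 ± 0.39. The accessory genes hupF (bsl6938) and hupI (bsl6935) changed 5.84-fold and 3.62-fold. In the list of hydrogen uptake and hydrogenase maturation, 16 of 32 tested genes changed on the hydrogenase side and 0 on the opposite side, where 0 reached an unadjusted p under 0.05 (limma); adjusted over the list alone the counts were also 16 and 0. The block tagged bll69, bsl69 and blr69 held 15 of the 16, out of 20 tested, with a mean log2 of 1.51. Of the 10 tested members in the other block of hup and hyp genes, tagged blr17 and bsr17, 0 changed (limma, 1 at an unadjusted p under 0.05), and the largest size among them was 0.49. The remaining changed member, hupA (bll6175, 3.28-fold), carries a symbol that is also used for a histone-like DNA-binding protein. The list was called by camera (adjusted p = 6.59e-06, and adjusted p = 0.588 with an estimated correlation) and by fry (adjusted p = 0.00339). Without replicate 2, 9 of its genes passed.

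**Figure D2:**
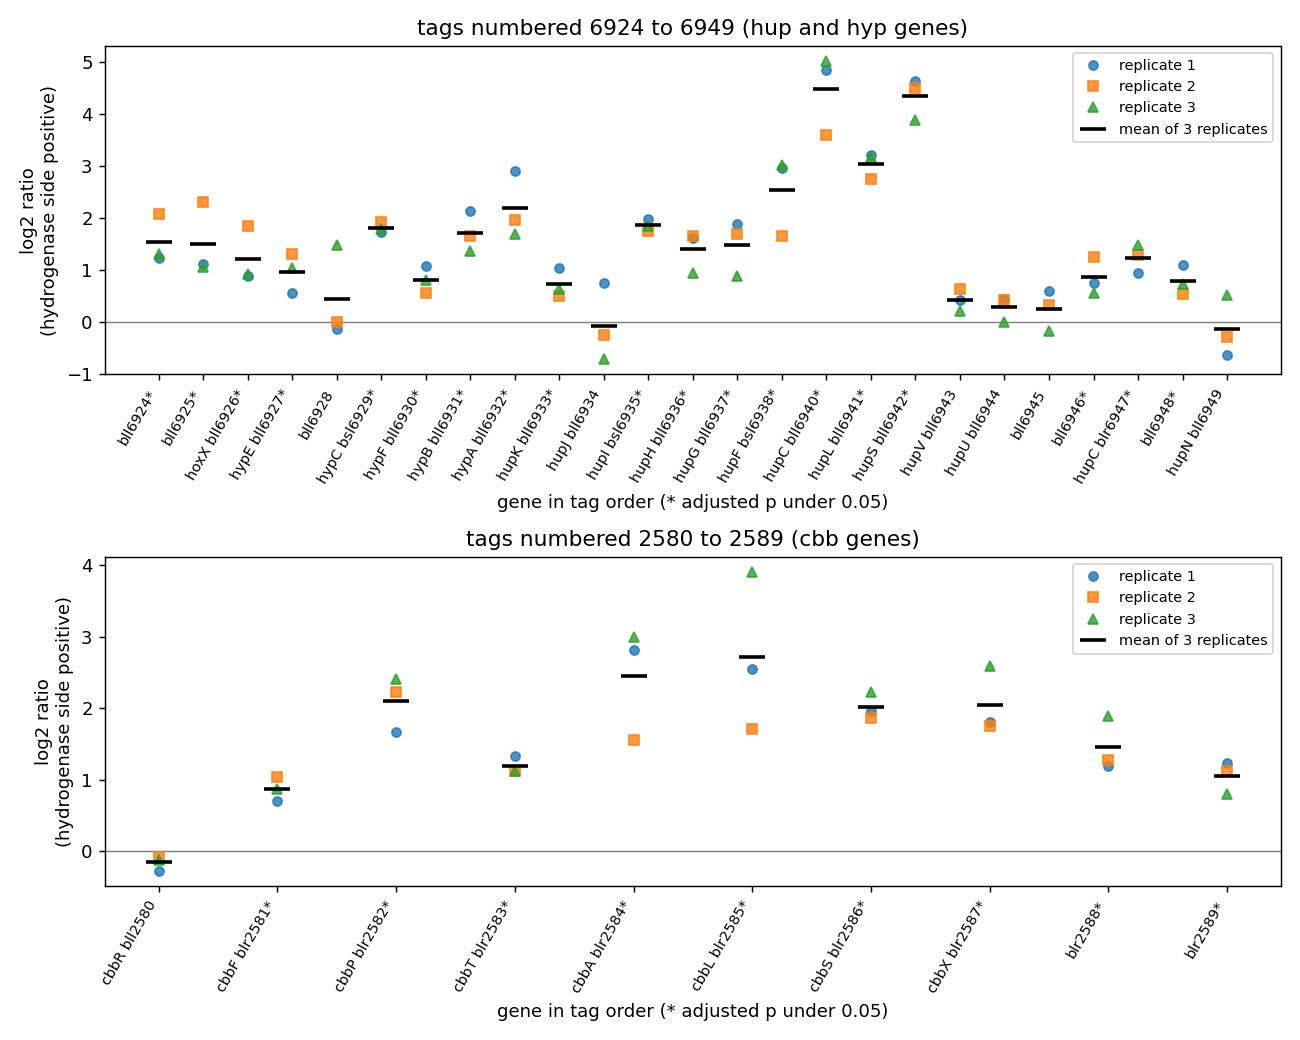
Log2 ratios with the hydrogenase side positive (vertical axis) for genes in tag order (horizontal axis), in the tag ranges of the hup and hyp genes (upper panel) and of the cbb genes (lower panel). Points are the 3 replicates, each the mean of 2 dye-swapped arrays, bars their mean, and an asterisk an adjusted p under 0.05; hupC, hupL and hupS stand highest at 4.49, 3.05 and 4.35, and cbbR lies at -0.15.

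Calvin cycle genes, which fix carbon dioxide, changed on the same side as the hydrogenase genes, 7 of 9 tested and 0 on the opposite side (limma, 0 there at an unadjusted p under 0.05); adjusted over the list alone the counts were the same. The large and small subunit genes of ribulose bisphosphate carboxylase, cbbL (blr2585) and cbbS (blr2586), changed by log2 sizes of 2.72 ± 1.11 and 2.02 ± 0.19 (SD, n = 3), with cbbL at 2.13 without replicate 3. The aldolase gene cbbA (blr2584) changed 5.48-fold, the phosphoribulokinase gene cbbP (blr2582) 4.28-fold, the carboxylase activase gene cbbX (blr2587) 4.14-fold, the transketolase gene cbbT (blr2583) 2.29-fold and the fructose bisphosphatase gene cbbF (blr2581) 1.83-fold. The divergent regulator gene cbbR (bll2580) had a log2 ratio of -0.15 ± 0.10 (adjusted p = 0.459), and cbbY (bll6838), chosen after its values were seen, lay at 0.01. Without replicate 2, cbbT and cbbF did not pass (adjusted p = 0.0611 and 0.122), which left 5 genes of the list. Camera called the list (adjusted p = 4.29e-05, and adjusted p = 0.588 with an estimated correlation), as did fry (adjusted p = 0.0482). A carbonic anhydrase gene, cah (bll1137), was the 1 of 2 tested that changed, 2.38-fold on the hydrogenase side, and it did not pass without replicate 2 (adjusted p = 0.0823).

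Energy metabolism changed in parts. In the ATP synthase list 5 of 8 genes changed on the hydrogenase side and 0 on the opposite side (limma, 0 there at an unadjusted p under 0.05), and 7 adjusted over the list alone. The largest were atpC (bsl1187) at a log2 size of 1.67 ± 0.31 (SD, n = 3) and atpB (bll1185) at 1.55 ± 0.34, which together with atpA (bll1188, 1.23) sit in a tag block separate from atpA (bll0442, 0.83) and atpD (bll0440, 0.72). The last 3 were chosen after their values were seen. Camera called the list (adjusted p = 6.04e-05, and adjusted p = 0.588 with an estimated correlation), as did fry (adjusted p = 0.0482), and the number of its genes that passed was 3 without replicate 1 and 2 without replicate 2. Among terminal oxidases and cytochrome bc1, coxB (blr1170, 3.40-fold) and coxA (blr1171, 2.32-fold), subunits of a cytochrome c oxidase, changed on the hydrogenase side. They were 2 of 14 tested, and without replicate 2 coxA did not pass (adjusted p = 0.0725). The list was not called by camera (adjusted p = 0.602) or fry (adjusted p = 0.129), while fry with the replicate block called it (adjusted p = 0.0274). With that block 3 of its genes passed on the hydrogenase side and 1 on the opposite side. The symbols chosen for carbon monoxide dehydrogenase matched 4 genes that stand among cytochrome oxidase genes by tag, so the list cannot be taken to measure that enzyme, and genes named cutL and cutM were not in it. Of the 4, coxG (blr1174, 2.19-fold) and coxE (blr1172, 1.75-fold), with tags close after those of coxB and coxA, changed on the hydrogenase side, and neither passed without replicate 2 (adjusted p = 0.121 and 0.123) or without replicate 3 (adjusted p = 0.0627 and 0.0601). The other members coxM (bll3785) and coxF (bsr1173) had log2 ratios of -0.50 and -0.20 that did not pass, and the list was not called (adjusted p = 0.602). Adjusted over it alone 2 passed on the hydrogenase side and 1 on the opposite side. Of 10 tested genes whose symbol starts with cox, 4 changed on the hydrogenase side and 1 on the opposite side (limma, over all genes). Of 13 tested genes of the tricarboxylic acid and glyoxylate cycles 0 changed (limma, 2 at an unadjusted p under 0.05, and 1 with the replicate block), the 8 of smallest p running from fumC (bll0286) at -0.53 to sdhA (blr0514) at 0.60. Of 13 genes of NADH dehydrogenase 0 changed (limma, 0 at an unadjusted p under 0.05), with nuoE (bll3138) at 0.33 and nuoM (bll4905) at 0.30.

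Of 51 ribosomal protein genes 11 changed on the hydrogenase side and 0 on the other (limma, 0 there at an unadjusted p under 0.05); adjusted over the list alone 16 passed. The largest were rpmC (bsl5392, 2.29-fold) and rpsQ (bsl5391, 2.18-fold). The list mean was 0.41, and it was 0.20 without replicate 1 and 0.62 without replicate 3. Camera called the list (adjusted p = 3.15e-05, and adjusted p = 0.842 with an estimated correlation), and fry did not (adjusted p = 0.388, and 0.193 with the replicate block). Without replicate 2, 0 ribosomal protein genes passed, and with the replicate block 17 did. Of 32 chaperone and heat shock genes 3 changed, all on the hydrogenase side: groEL (blr5626) at a log2 size of 2.54 ± 1.40 (SD, n = 3), a second groEL (blr7533) at 1.35 ± 0.58 and dnaJ (bll0184), chosen after its values were seen, at 0.95. Adjusted over the list alone 6 passed on that side and 1 on the opposite side. Camera called the list (adjusted p = 0.0337, and adjusted p = 0.85 with an estimated correlation), but not without replicate 1 (adjusted p = 0.276), and fry did not (adjusted p = 0.519, and 0.193 with the replicate block). The first groEL had a size of 1.77 without replicate 1 and 3.14 without replicate 2. The 2 groEL genes did not pass without replicate 3 (adjusted p = 0.0733 and 0.0662). With the replicate block 10 chaperone genes passed on the hydrogenase side and 2 on the other, without replicate 1 these were 7 and 2, and without replicate 3 the count was 1 on the hydrogenase side.

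Some motility and surface genes changed on the hydrogenase side. Of 59 tested flagellar and chemotaxis genes 10 changed there and 0 on the opposite side (limma, 1 there at an unadjusted p under 0.05), and 17 adjusted over the list alone. They included 2 genes for the chemotaxis response regulator cheY, blr2194 (4.78-fold) and blr2342 (2.78-fold), of which blr2342 did not pass without replicate 2 (adjusted p = 0.103). The list mean was 0.38, and camera called it (adjusted p = 6.93e-05, and adjusted p = 0.834 with an estimated correlation). Fry did not (adjusted p = 0.178), and with the replicate block it did (adjusted p = 0.0118). Without replicate 2, 1 gene of the list passed, and with the replicate block 18 passed on the hydrogenase side and 1 on the other. In the exopolysaccharide list 4 of 7 changed on the hydrogenase side and 0 on the opposite side (limma, 0 there at an unadjusted p under 0.05), and 5 adjusted over the list alone. The 4 were exoN (blr1499, 2.78-fold), exoU (blr7573, 2.16-fold), exoT (blr7577, log2 1.01) and exoB (blr7578, log2 0.60), the last 2 chosen after their values were seen. Camera called the list (adjusted p = 0.00321, and adjusted p = 0.588 with an estimated correlation). Fry did not (adjusted p = 0.0525), and with the replicate block it did (adjusted p = 0.000586). The number of members that passed was 2 without replicate 1 and 1 without replicate 2. Without replicate 2 exoU did not pass (adjusted p = 0.0657), although its log2 ratios in the 3 replicates were close, at 1.11, 1.08 and 1.15. The pilin gene pilA (bsl6587) changed 6.44-fold and 2 genes named ctpA, bsl1442 and bsl7141, changed by log2 sizes of 3.34 ± 1.07 and 3.28 ± 1.42 (SD, n = 3, 10.1-fold and 9.69-fold) on the hydrogenase side. Without replicate 3 the sizes were 3.95 and 4.09 (15.5-fold and 17.1-fold). The second of these genes did not pass without replicate 2 (adjusted p = 0.0789) and differed between the replicates (limma on 6 arrays, adjusted p = 0.000982). The ribonucleotide reductase gene nrdE (bll4274) changed by a log2 size of 3.32 ± 0.79 (SD, n = 3) on that side.

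**Figure D3:**
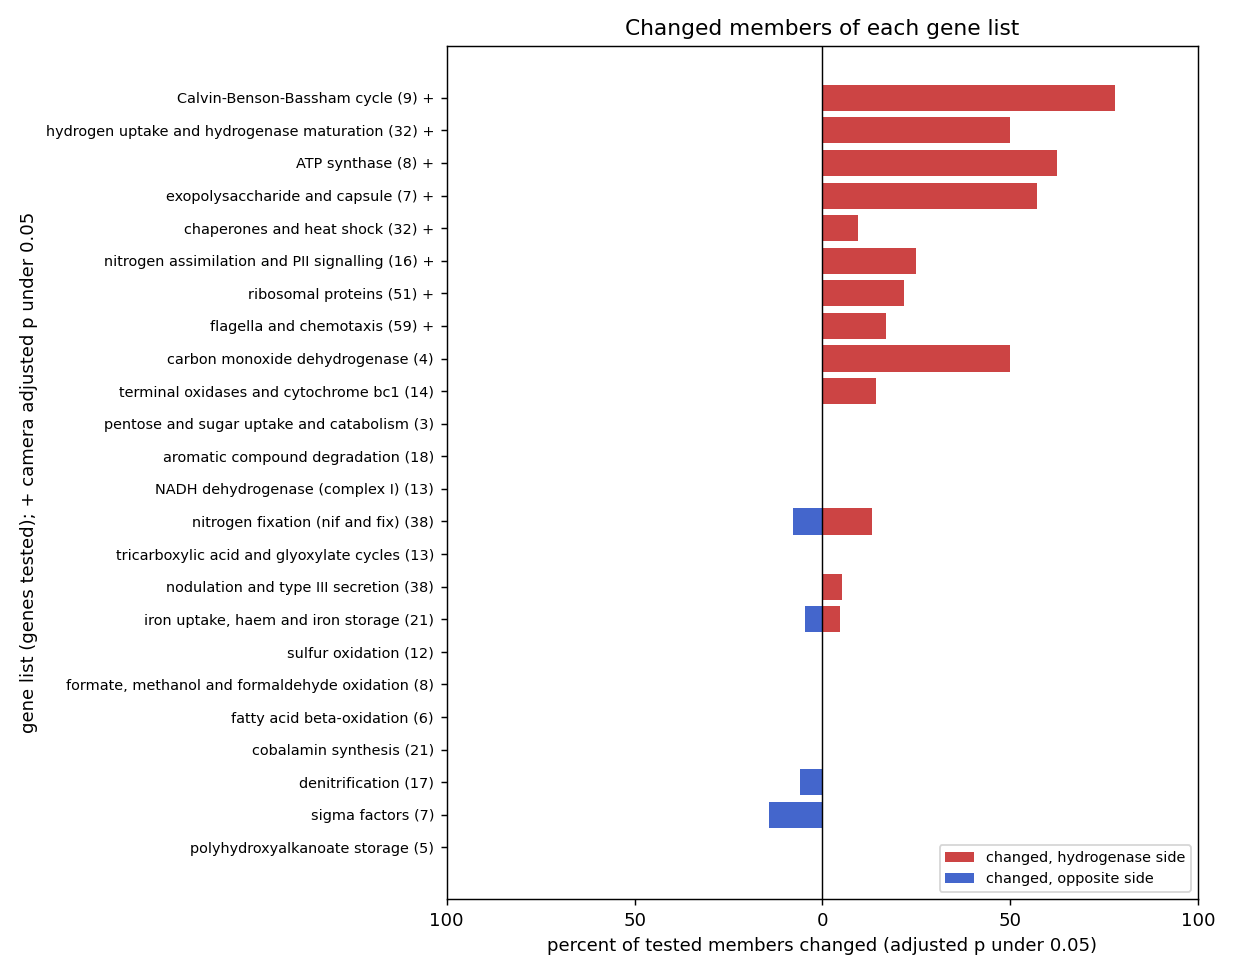
Percent of tested members that changed (horizontal axis) in each of the 24 tested gene lists (vertical axis, number of genes tested in brackets), to the right on the hydrogenase side and to the left on the opposite side; a plus sign marks a camera adjusted p under 0.05. The 8 marked lists all extend to the right, and nitrogen fixation extends both ways, with 5 members on the hydrogenase side and 3 on the opposite side.

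Nitrogen genes that changed stood on both sides. In the nitrogen fixation list, the nitrogenase genes nifD (blr1743) and nifK (blr1744) changed by log2 sizes of 1.51 ± 0.62 and 1.37 ± 0.14 (SD, n = 3) on the hydrogenase side, with nifX (blr1747) at 1.35, nifN (blr1746) at 0.86 and fixC (blr1774) at 0.77. A further nitrogenase gene, nifH (blr1769), chosen after its values were seen, had a log2 ratio of 0.45 and did not pass. On the opposite side stood 3 genes named fixK, a family of regulators of the response to low oxygen: bll2757 at a size of 3.87 ± 0.64 (14.7-fold), bll3466 at 1.57 ± 0.37 and bll7696 at 1.08 ± 0.52. With 5 and 3 of 38 tested genes on the 2 sides, or 7 and 4 adjusted over the list alone, the list was not called (adjusted p = 0.602). Leaving out replicate 1, 2 or 3 ended the calls of nifN (adjusted p = 0.0657, 0.0784 and 0.0683) and fixC (adjusted p = 0.0695, 0.103 and 0.0641). The gene nifD did not pass without replicate 3 (adjusted p = 0.0533), nifX without replicate 2 (adjusted p = 0.0585) and the fixK gene bll7696 without replicate 2 or 3 (adjusted p = 0.144 and 0.0671). The counts of the list were 3 and 5 without replicate 1, 3 and 2 without replicate 2, 2 and 2 without replicate 3, and 10 and 6 with the replicate block. Of 16 nitrogen assimilation genes tested, 4 changed on the hydrogenase side and 0 on the opposite side (limma, 0 there at an unadjusted p under 0.05), and 6 adjusted over the list alone. They were the two-component genes ntrX (blr4490, 4.30-fold) and ntrY (blr4489, 3.22-fold), the PII protein gene glnK (blr0606, log2 0.98) and the glutamate synthase gene gltB (blr7743, log2 0.98), the last 2 chosen after their values were seen. Camera called this list (adjusted p = 0.0267, and adjusted p = 0.588 with an estimated correlation), but not without replicate 3 (adjusted p = 0.128) or on the arrays with heterotrophy in Cy5 alone (adjusted p = 0.0521). Fry did not call it (adjusted p = 0.0546), and with the replicate block fry did (adjusted p = 0.000534) and 7 of its genes passed. Of 17 denitrification genes 1 changed, napE (bsr7036) of the periplasmic nitrate reductase, 3.33-fold on the opposite side, and it did not pass without replicate 2 (adjusted p = 0.159) or without replicate 3 (adjusted p = 0.0976). Adjusted over the list alone 0 denitrification genes passed. With the replicate block 2 denitrification genes passed on the hydrogenase side and 3 on the opposite side, and without replicate 1, 3 passed on the opposite side. In the nodulation list nodA (blr2025, 3.66-fold) and nodQ (bll1475, 3.07-fold) changed on the hydrogenase side, 2 of 38 tested. The mean log2 ratio of the list was -0.005, and camera did not call it (adjusted p = 0.602). Without replicate 2 neither passed (adjusted p = 0.0509 and 0.0695), and without replicate 3 nodQ did not (adjusted p = 0.0666). Adjusted over the list alone 1 nodulation gene passed, on the hydrogenase side. With the replicate block 3 nodulation genes passed on the hydrogenase side and 1 on the opposite side.

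On the opposite side, neighbouring genes for the synthesis of biotin and of a pantothenate precursor followed fixK in size among changed genes with a symbol. The biotin synthase gene bioB (blr2095) changed by a log2 size of 3.26 ± 0.27 (SD, n = 3, 9.60-fold, adjusted p = 0.00335) and the aspartate decarboxylase gene panD (blr2096) by 2.76 ± 0.63 (6.77-fold, adjusted p = 0.00893). Most genes sharing their symbols did not change: 2 of 5 tested genes named bio and 1 of 6 named pan did (limma), groups formed after the values were seen. The quinoprotein alcohol dehydrogenase gene exaA (blr6207) changed 5.28-fold, the malonate decarboxylase gene mdcA (bll0270) 4.12-fold, dnaC (bll4072) 3.13-fold and the threonine dehydratase gene ilvA (bll5902) 2.78-fold. Without replicate 2, mdcA and ilvA did not pass (adjusted p = 0.0691 and 0.0867). The gene hemA (bll1200), for the first enzyme of haem synthesis in this group of bacteria, changed 3.59-fold, but it did not pass without replicate 2 (adjusted p = 0.133), without replicate 3 (adjusted p = 0.0509) or with each array centred on its median (adjusted p = 0.0543). Centring also ended the calls of napE (adjusted p = 0.052) and of ahpD (bll1776, adjusted p = 0.0562), the 1 of 2 tested oxidative stress genes that changed, 1.56-fold on the opposite side. Leaving out replicate 1, 2 or 3 ended the call of ahpD too (adjusted p = 0.134, 0.133 and 0.0955).

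Other lists changed little. Of 21 iron and haem genes hemE (bll2399) changed 1.74-fold on the hydrogenase side and hemA on the opposite side, and of 7 sigma factor genes ecfA (bll6484) changed 1.66-fold on the opposite side. Leaving out replicate 1, 2 or 3 ended the call of ecfA (adjusted p = 0.113, 0.12 and 0.0727), and hemE did not without replicate 2 (adjusted p = 0.136). With the replicate block 2 sigma factor genes passed on the opposite side, and 2 iron and haem genes on the hydrogenase side and 3 on the opposite side. The iron and haem counts were 1 and 2 without replicate 1, and 3 and 0 without replicate 3. Adjusted over the list alone, 1 sigma factor gene passed on the hydrogenase side and 3 on the opposite side, and 1 and 0 of the iron and haem genes. No member passed by limma in the lists for polyhydroxyalkanoate storage (0 of 5, and 2 at an unadjusted p under 0.05), cobalamin synthesis (0 of 21, and 2 at an unadjusted p under 0.05), aromatic compound degradation (0 of 18, and 5), sulfur oxidation (0 of 12, and 1), pentose and sugar use (0 of 3, and 1), fatty acid oxidation (0 of 6, and 0) and the oxidation of formate, methanol and formaldehyde (0 of 8, and 0). Their leading members included phbC (bll6073) at -0.83, cobH (blr3265) at -0.72, pcaC (blr5669) at 0.55, soxX (bll1014) at -0.41, xylA (blr1120) at 0.67, fadB (bll2946) at -0.45 and pqqA (bsr6735) at -0.64. Adjusted over each list alone 1 pentose and sugar gene passed and 0 genes of the other 6 lists. With the replicate block 4 aromatic degradation genes and 1 pentose and sugar gene passed on the hydrogenase side, and 2 polyhydroxyalkanoate and 2 cobalamin genes on the opposite side. Leaving out replicate 2 gave 1 aromatic degradation gene, leaving out replicate 1 gave 1 polyhydroxyalkanoate gene, and scaling the arrays gave 1 pentose and sugar gene and 1 cobalamin gene. None of these lists was called by camera or fry. With the replicate block, fry called polyhydroxyalkanoate storage (adjusted p = 0.00526), cobalamin synthesis (adjusted p = 0.00363) and sigma factors (adjusted p = 0.0105) on the opposite side and pentose and sugar use (adjusted p = 0.0274) on the hydrogenase side.

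In all, 8 of 24 lists were called by camera, 8 on the hydrogenase side and 0 on the opposite side, where 0 reached an unadjusted p under 0.05. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05), fry called 3, all among the 8, and fry with the replicate block 11, of which 6 were among the 8. The unadjusted camera p of the hydrogenase list rose from 2.74e-07 to 0.0277, although its estimated correlation, -0.031, lay below the preset 0.01. The 0 calls therefore also reflect the 2 residual degrees of freedom of that run, and do not show that correlation within the lists explains the 8 calls. Camera compares the moderated t-statistics of a list, not its log2 ratios, with those of all other genes. Its direction differed from the sign of the mean log2 ratio for the tricarboxylic acid cycle (mean 0.01), iron and haem (mean -0.04) and aromatic degradation (mean 0.08). For the terminal oxidases the mean (0.25) and median (-0.01) differed in sign. On the arrays with heterotrophy in Cy3 alone, nifN, coxE, coxG and ecfA did not pass, and on those with heterotrophy in Cy5 alone, hemA, nodQ, ahpD, ecfA, napE, rpmC, fixC and the fixK gene bll7696 did not. Scaling the arrays ended the calls of hemA, ahpD, napE, coxE and bll7696. Of the 60 named genes that passed, 56 passed without replicate 1, 36 without replicate 2 and 47 without replicate 3. Such losses also reflect the lower power of 2 replicates, and alone they do not single out genes that depend on 1 replicate.

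The dye comparison asked how far an array depends on which condition carried which dye. The difference between the 2 arrays of a replicate passed the test in 0 of 7853 genes (limma, 786 at an unadjusted p under 0.05, smallest adjusted p = 0.0909). Replicate 3 decided that count: without it 1287 genes passed, without replicate 2 there were 11 and without replicate 1 there were 0. Dye differences correlated across genes at 0.58 between replicates 1 and 2, and at -0.113 and -0.0928 between each of them and replicate 3. The median absolute difference between the arrays of a replicate was 0.26, 0.244 and 0.141 on the log2 scale in replicates 1, 2 and 3.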

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

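The fit with no array turned and fry with the replicate block were chosen after the data were seen. The replicate numbers pair the arrays, and taking all 6 arrays with the replicate block as a random effect raised the number of changed genes from 885 to 1825 (1085 on the hydrogenase side and 740 on the opposite side). With a dye term as well it was 1537 (927 and 610), and with all 6 arrays taken as independent 2707 (1496 and 1211), since these count 6 arrays where the reported test counts 3 replicates. Stricter criteria gave fewer: 125 (71 and 54) at an adjusted p under 0.01, all 125 at least 2-fold, and 150 (90 and 60), all at least 2-fold, for treat against a 1.5-fold change. With no array turned 0 genes passed and 0 at least 2-fold (limma, 786 at an unadjusted p under 0.05). The change between the conditions cancels in that fit, which tests the same quantity as the dye comparison and is no separate result. Leaving out a replicate gave 221 to 879 genes, 136 to 536 on the hydrogenase side, 85 to 343 on the opposite side and 221 to 648 of at least 2-fold, lowest without replicate 2. Genes with a dye effect ranged from 0 to 1287. The causes of these last differences were not tested. Each orientation alone (963 and 620), centring (816), scaling (898), robust eBayes (861), rows on their own (925) and genes with a value in at least 2 replicates (885) stayed within 1.5 times of the count. Of 24 lists tested, camera called 8 and, with an estimated correlation, 0 (1 at an unadjusted p under 0.05), fry called 3, all among the 8, and fry with the replicate block 11, of which 6 were among the 8. The run with an estimated correlation rests on 2 residual degrees of freedom, so its 0 calls do not measure correlation alone. No list or named gene that passed under a setting run for it had its sign turned in another. The block kept all 60 named calls and added 8. Centring moved no array median by more than 0.0884. Signal over background is unknown, and the number of arrays limits the precision.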

Other observations

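The tests of the ratio's direction and of the fix genes were chosen after the results were seen, as were the runs of neighbouring genes and the groups by symbol described first. Genes with consecutive tag numbers on the same strand formed 12 runs of 4 or more changed genes on the same side, 62 genes in all, against at most 2 runs in 1000 shuffles of the genes over the tags. The longest was the cbb run from blr2581 to blr2589, of 9 genes with a mean log2 of 1.77, which takes in blr2588 and blr2589 beyond the cbb symbols. Runs without a symbol on the hydrogenase side were blr4257 to blr4263, of 7 genes (mean 1.99, from 0.95 to 2.95), and 2 of 4 genes each, bll5843 to bll5846 (mean 2.11) and bll1565 to bll1568 (mean 1.00). A run of 6, blr1477 to blr1482, held cysH, a gene of sulfate assimilation (mean 1.87), and a run of 4, bll6500 to bll6503, held ilvI and ilvH, the subunits of acetolactate synthase (mean 1.26). The run on the opposite side, blr0845 to blr0848, had 4 genes without a symbol and a mean of -1.21.

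Grouped by the first 3 letters of their symbols, 15 of 103 groups were called by camera, 14 on the hydrogenase side and 1 on the opposite side, and 0 with an estimated correlation (1 at an unadjusted p under 0.05). As for the lists, the run with an estimated correlation rests on 2 residual degrees of freedom, so its 0 calls do not measure correlation alone. Genes named cspA, for cold shock proteins, had a mean log2 of 1.07, with 3 of 8 changed (adjusted p = 0.000591, and adjusted p = 0.892 with an estimated correlation). Genes named ctp had a mean of 1.00, with 7 of 13 changed (adjusted p = 0.000746, and adjusted p = 0.892 with an estimated correlation). The nif genes had a mean of 0.47, with 4 of 15 changed, on the hydrogenase side (camera adjusted p = 0.0332, and adjusted p = 0.892 with an estimated correlation). The fix genes were not called (mean -0.28, camera adjusted p = 0.473), with 1 of 22 changed on the hydrogenase side and 3 on the opposite side. The group on the opposite side was bio, for biotin synthesis, with a mean of -1.25 and 2 of 5 changed (adjusted p = 0.00594, and adjusted p = 0.892 with an estimated correlation).

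Genes with neighbouring tags changed together. Among 4990 neighbouring pairs on the same strand the log2 ratios correlated at 0.449 (95% bootstrap interval 0.414 to 0.484), and among 2448 pairs on opposite strands at 0.123 (0.083 to 0.166). As the only source, a local array artefact shared by spots laid out in tag order would make opposite-strand pairs correlate like same-strand pairs. They correlated less, but a smaller artefact that adds to both kinds of pairs was not tested. The dye differences of opposite-strand pairs correlated at 0.058 (0.0218 to 0.0942), against 0.117 on the same strand. That excess in the dye differences has no tested cause. The difference of 0.326 between the 2 kinds of pairs (permutation p = 1e-04, the smallest that 10000 permutations can give) is consistent with co-transcription of neighbouring same-strand genes, as a hypothesis. The layout of the spots was not used here, and the correlation of 0.123 on opposite strands stays without a tested cause.

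All 23 changed members of the hydrogenase and Calvin cycle lists lay on 1 side, which fixes their relation to each other but not the condition they were higher in. If the deposited ratio is Cy3 over Cy5, the 23 genes were higher under arabinose-supplemented chemoautotrophy, and these are the genes whose products take up hydrogen and fix carbon dioxide in chemoautotrophic growth. If it is Cy5 over Cy3, the 23 genes were lower in that condition than in heterotrophy, and no cause for this was tested. The values alone cannot tell the 2 readings apart, because the sign of the ratio enters every gene alike. No gene of known direction is measured apart from it. The array titles name the Cy3 condition first, so their order flips with the sign. Read as a ratio, that order gives Cy3 over Cy5, and the role of these genes in chemoautotrophic growth goes with the same reading. Whether the titles state a ratio or only the dyes is not given, and neither point was tested.

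Of the 8 genes of fixNOQP and fixGHIS, which encode a high-affinity cytochrome oxidase and its assembly, 6 differed between the 3 replicates (limma on 6 arrays, adjusted p under 0.05; fixI and fixS did not, at adjusted p = 0.0591 and 0.0855) and 0 passed the comparison of the conditions (limma, smallest adjusted p = 0.131). The gene fixP (blr2766) had log2 ratios of 2.78, 0.77 and 0.16 in replicates 1, 2 and 3, fixH (blr2768) 1.94, -0.17 and -1.18, and fixN (blr2763) -0.03, -1.21 and -1.98. A dye bias pushes the 2 arrays of a replicate apart and cancels in their mean. The deviations from the mean of the 3 replicates agreed between the 2 orientations (correlation 0.956 over the 8 genes, 95% bootstrap interval 0.912 to 0.98). That agreement restates the pattern for which the genes were chosen, and each orientation's mean was subtracted first. It is therefore no separate test of a dye bias. Noise of single arrays is argued against for the 6 genes, whose p-values are adjusted over all genes tested. The median difference between replicates was 1.03, against 0.224 between the 2 arrays of a replicate, and 0.291 against 0.204 over all genes, with the 8 chosen after their values were seen. A difference between the culture pairs or RNA preparations, which both arrays of a replicate share, stays open. No biological explanation was tested.

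Between the 3 replicates 1542 genes differed (limma on 6 arrays, 2825 at an unadjusted p under 0.05), of which 247 also changed between the conditions. These p-values rest on the spread between the 2 arrays of the same extracts. The genes given here were chosen after their values were seen. The nitric oxide reductase gene norC (blr3214) had log2 ratios of -2.78, -2.55 and 2.20 in replicates 1, 2 and 3, and tspO (bll5190) 3.14, 2.71 and -1.12. The chaperonin gene groES (blr5625) had 4.94, 1.73 and 1.94, and clpB (blr1404) 3.92, 0.60 and 1.60.

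With 3 replicates there are 4 patterns of sign, too few for a share under 0.05. The real pattern, 1 of the 4, gave 885 genes, and the highest of the others gave 0. For the gene lists 2 of the 4 patterns gave at least the 8 lists called, the highest of the others 9, with replicate 1 turned. All 4 gave 0 genes with a dye effect (limma, 786 at an unadjusted p under 0.05 in the real pattern).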
